A study of Mus musculus with 121 samples.

How the data were processed

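The samples were mouse G1E-ER4 cells and sublines of them. RNA-seq (18 libraries), TT-seq (6 libraries), ChIP-seq and Micro-C were measured with the groups and replicates given in the labels. Replicates are numbered in the labels without saying whether they are separate cultures, so part of them may be technical.

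RNA-seq values are estimated counts per gene symbol that the authors deposited as whole numbers. Salmon 0.13.1 and DESeq2 are named for these samples with the mouse build mm9, per the submitters' processing notes, and the transcript set is not given in the sources used here. Salmon estimates need not be whole, so these were rounded before deposit. TT-seq values are counts per gene that the authors deposited for mouse genes and, separately, for the Drosophila spike-in (500 ng of S2 cell RNA per 100 µg of cell RNA, per the labels). Trim Galore 0.6.10, STAR and SAMtools are named with the builds mm9 and dm6, per the submitters' processing notes, and HTSeq by the name and summary lines of the deposited counts. The library kits mark strand, but the strand setting of the counting and whether introns were counted are not given in the sources used here. Lines that name no gene were left out, the largest being reads without a feature (17.2% to 22.2% of a TT-seq library) and ambiguous reads (0.391% to 0.529%). Bowtie2, MACS2 2.2.7 and deepTools 3.5.1 are named for the ChIP-seq and Micro-C samples with mm9, per the submitters' processing notes. The threshold of the peaks, the way replicates were combined and the tools that called loops, boundaries and domains are not given in the sources used here. Peak lists give positions without a score.

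Each count table was analysed with edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr by group and quasi-likelihood F-tests, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Of 55351 gene symbols in the time series 24752 had no counts and 15157 were tested. In the table of untreated lines 22493 were listed, 8374 had no counts and 10892 were tested, and in TT-seq 25208 were listed, 7016 had no counts and 11218 were tested. All groups of a table entered 1 fit, without a replicate term. Tests, samples, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except for those named below as chosen afterwards. Pairing by replicate number was checked by correlating the deviations of libraries from their group means. In TT-seq libraries of the same number deviated together (0.55, 0.66 and 0.40, against at most −0.09 for other numbers), so the numbers pair the TT-seq libraries, and the pairing comes from the data, not from the labels. In the untreated lines the correlations were 0.74, 0.68 and 0.63 with 2 libraries per group, which is treated as a visible batch. Counts of calls with the number as a block are given for TT-seq, the untreated lines and part of the time series, and list results with it only in part.

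The text names genes by a rule. For TT-seq and for RNA-seq at 4, 24 and 48 h these are Yy1, then the 6 highest and 6 lowest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 3 and groups that do not overlap, leaving out predicted and clone-named genes, and up to 4 members with the smallest p of each list described. For the other comparisons 4 in each direction were taken. Genes so named may be followed in other comparisons. Some genes that meet the rule are not reported here.

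Gene lists (28) covered the erythroid program, heme and iron, stem and progenitor regulators, myeloid, megakaryocyte, mast cell, lymphoid and pluripotency markers, oxidative phosphorylation, mitochondrially encoded genes, mitochondrial and cytosolic ribosomal proteins, ribosome biogenesis, S phase, G2 and M phase, replication-dependent histones, immediate early genes, p53 targets, integrated stress, heat shock, interferon response, cholesterol biosynthesis, glycolysis and hypoxia, aminoacyl tRNA synthetases, the proteasome, splicing factors, chromatin architecture factors, and Polycomb and INO80 subunits. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, with fry and with the replicate block. Expression per library is given as log2 CPM with a prior count of 2.

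Peaks, loop anchors and boundaries were intersected with bedtools 2.31.1, counting an overlap of at least 1 bp as shared. Shares have Wilson 95% intervals, which cover counting error only. Chance overlap came from 200 circular shifts of the peaks along their chromosomes, whose lengths were taken from the largest end in the lists. Shares were compared by Fisher's exact test (two-sided, SciPy 1.17.1) across peaks or loops, and the 40 comparisons between stages were adjusted by Benjamini-Hochberg. The median peak is 400 bp wide, and 1440 bp for untreated H3K27ac. No annotation of mm9 was used, so peaks and loops were not assigned to promoters or genes. The spike-in ratio was tested by an exact permutation test. Figures were drawn with matplotlib 3.10.9.

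The procedures were tested on simulated data with 200 genes changed by 1 on the log2 scale. Of these, 61.5% were recovered with the spread of the time series (5 false calls), none with that of the untreated lines (no false calls) and 80.5% with that of TT-seq (19 false calls). These fits had no replicate block. A list of 40 genes moved by 0.5 was called in all 3 tables and no other list was. Genes were drawn independently of each other, so this cannot show how often lists of genes that move together are called falsely. Of 800 planted peak overlaps all 800 were found, and 10 of the peaks without a planted overlap also met one. Alternatives tried were DESeq2 1.42.0, limma voom, RLE factors, no filter, a stricter filter (at least 10 counts in each library of a group and a mean of at least 50), the replicate block, only the groups compared, an absolute log2 fold change of at least 1, spike-in library sizes, each library left out, stricter overlaps and widened anchors and boundaries. Pol II ChIP-seq, the inputs and asynchronous YY1 ChIP-seq of G1E-ER4 cells were not analysed here, nor were coverage tracks.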

Results

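The study asked what happens to chromatin binding, chromatin contacts and transcription when the transcription factor YY1 is removed from erythroid cells, and whether this depends on the phase of the cell cycle. The cells were G1E-ER4, a mouse erythroblast line derived from embryonic stem cells without functional GATA1 and carrying a hormone-activated GATA1. In the YY1-AID subline YY1 is fused to an auxin-inducible degron, a tag that leads to breakdown of the protein once auxin is added. The 121 samples comprised RNA-seq, TT-seq (sequencing of RNA labelled during a 5 min pulse of 500 µM 4-thiouridine), ChIP-seq and Micro-C, a chromosome conformation assay that fragments chromatin with micrococcal nuclease. RNA-seq covered 0, 4, 24 and 48 h of auxin (3 libraries each) and, in a separate table, untreated parental cells, the YY1-AID subline and another YY1-AID subline named subline 3 (2 libraries each). TT-seq covered untreated cells and 4 h of auxin (3 libraries each). ChIP-seq came as peak lists, 1 per condition, from 2 or 3 libraries each. Micro-C came as lists of loops, boundaries and domains merged over untreated and auxin samples, for asynchronous cells (5 libraries per treatment) and cells in mid-G1 (4 per treatment). Total gene counts per library ranged from 25.1 to 26.2 M in the time series, from 35.2 to 44.9 M in the untreated lines and from 30.2 to 53.5 M in TT-seq. Values after ± are standard errors of log2 fold changes unless named as SD.

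YY1 binding was largely lost from the peak lists after 4 h of auxin. Asynchronous YY1-AID cells had 41163 YY1 peaks before auxin and 3713 after it. Of the untreated peaks 3108 (7.55%, Wilson 95% interval 7.3 to 7.81) overlapped an auxin peak. A second YY1 antibody gave 9164 untreated and 2044 auxin peaks, with 19.6% retained (18.8 to 20.4). Of its untreated peaks 87.3% were also peaks of the first antibody. After auxin, 1171 of the 3713 peaks of the first antibody (31.5%) were also auxin peaks of the second. Of the 3108 kept peaks, 1167 overlapped an auxin peak of the second antibody too. Peaks that stayed after auxin more often overlapped an untreated peak of the second antibody (83.3% against 14.2% of lost peaks). They also more often overlapped H3K27ac, a histone mark of active promoters and enhancers (84.7% against 44.4%, odds ratio 6.92). Kept peaks less often overlapped LDB1, a cofactor of the GATA1 and TAL1 complex that tethers erythroid enhancers to promoters (12.3% against 18.3%, odds ratio 0.624, Fisher's exact test across peaks, p = 1.22e-18). Before auxin, 47.4% of YY1 peaks overlapped H3K27ac, 19.3% the cohesin subunit RAD21, 17.9% LDB1 and 14.5% the insulator protein CTCF, against 2.14%, 1.29%, 0.584% and 1.92% after random shifts of the peaks along their chromosomes (permutation by shifting, p = 0.005 for each, the smallest that 200 shifts can give). There was 1 list per condition and no peak score, so these shares have no replicate error, the intervals cover counting error only, and a smaller peak that was still called counts as kept. Yy1 mRNA itself did not pass the test at 4 h (0.11 ± 0.09), 24 h (−0.09 ± 0.09) or 48 h (0.05 ± 0.09), nor in TT-seq (0.16 ± 0.08), which says nothing about a protein that is removed after translation.

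**Figure D1:**
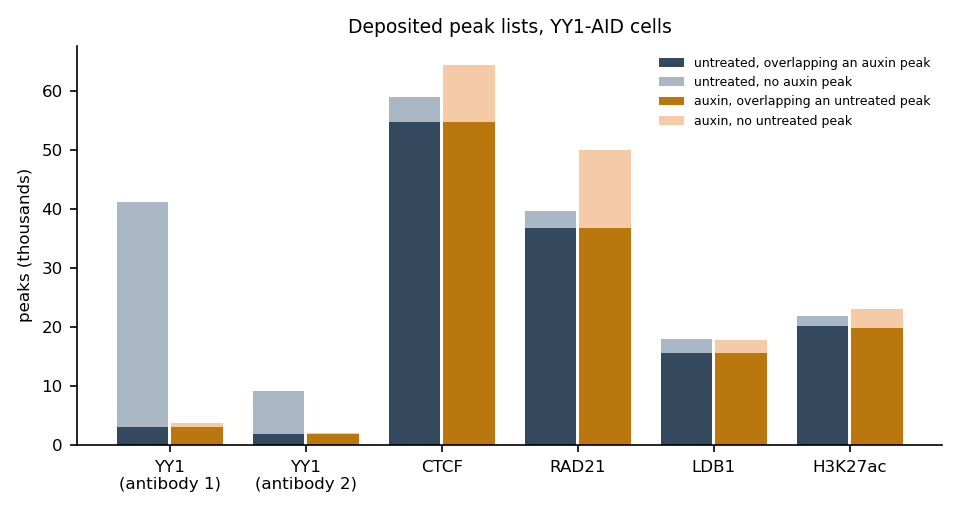
Number of peaks per list in asynchronous YY1-AID cells, untreated and after auxin, with the part of each list that overlaps the other list in the darker shade. Of the untreated peaks, 7.55% of YY1 (first antibody) and 19.6% of YY1 (second antibody) overlapped an auxin peak, against 92.8% of CTCF, 92.6% of RAD21, 87.1% of LDB1 and 91.8% of H3K27ac.

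CTCF, RAD21, LDB1 and H3K27ac peaks mostly stayed when YY1 was depleted. CTCF had 59085 peaks before and 64548 after auxin with 92.8% retained, LDB1 17914 and 17825 with 87.1%, and H3K27ac 21962 and 23016 with 91.8%. RAD21 had 39745 untreated peaks, 92.6% of them retained, and 50028 auxin peaks, of which 13229 had no untreated counterpart. Peaks that coincided with a YY1 peak were retained more often than the others for LDB1 (91.3% against 84.2%, odds ratio 1.98, Fisher's exact test, p = 9.93e-47), CTCF (94.6% against 92.6%, odds ratio 1.39, p = 1.2e-08) and H3K27ac (98.1% against 77.9%, odds ratio 14.8). With peaks reduced to 200 bp around their midpoints the last difference was smaller (77.0% against 63.4%, odds ratio 1.94, Fisher's exact test, p = 5.79e-83). RAD21 peaks did not pass the exact test of this difference (92.1% against 92.7%, p = 0.0687), and its direction turned when overlaps of at least 50% were asked for (92.8% against 92.5%). These tests are across peaks, which are not replicates. Shared peaks of YY1, CTCF, RAD21 and LDB1 have identical coordinates in both lists, so the lists were drawn from common intervals. H3K27ac peaks are not, and 67.0% of them were retained when each was reduced to 200 bp around its midpoint.

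Nascent transcription changed after 4 h of auxin, and the balance of rises and falls depended on the fit. In TT-seq, 237 genes were higher and 795 lower (edgeR quasi-likelihood test, adjusted p under 0.05, 11218 genes tested), 49 and 136 of them by more than 1 on the log2 scale. With the replicate number as a block 2541 were higher and 2833 lower, so that 47.3% of calls were higher against 23.0% without the block. The strongest increases were Thap1, a zinc finger transcription factor (1.71 ± 0.17), Cyb5d2, a heme-binding cytochrome b5 domain protein (1.68 ± 0.11), the oxidative stress enzymes Nqo1 (1.45 ± 0.14) and Srxn1 (1.23 ± 0.15), Clec4d (1.42 ± 0.11) and Unc119b (1.17 ± 0.16). The strongest decreases were Tsix, the antisense partner of Xist (−2.55 ± 0.15), the chromatin remodelling subunit Dpf3 (−2.41 ± 0.14), Ppp4r1l-ps (−2.39 ± 0.12), Ttc27 (−2.31 ± 0.09), the centrosomal Cdk5rap2 (−2.17 ± 0.09) and the DNA repair factor Shld1 (−2.04 ± 0.16). Tsix and the pseudogene Ppp4r1l-ps are uncertain, because the strand setting of the counting is not given in the sources used here and pseudogene reads can be split with the parent gene. Each value is from 3 libraries against 3. For these 12 genes every auxin library lay beyond every untreated library, which the rule for naming genes requires.

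Among the gene lists, oxidative phosphorylation was lower in TT-seq (9 of 76 genes lower and none higher, 10 adjusted over the list alone, camera adjusted p = 0.000862), with Atp5g2 at −0.56 ± 0.08 and Ndufb5 at −0.57 ± 0.09. Mitochondrial ribosomal proteins were lower as well (8 of 77, also 8 adjusted over the list alone, adjusted p = 0.0424), led by Mrps18b at −0.91 ± 0.10, but with the replicate block that list no longer passed (adjusted p = 0.157). Stem and progenitor regulators were lower (2 of 15, also 2 adjusted over the list alone, adjusted p = 0.0075), the 2 being Gata2 (−0.41 ± 0.09) and the growth factor receptor Kit (−0.39 ± 0.09). Cholesterol biosynthesis genes were higher as a list (median 0.20, adjusted p = 0.0256), although no member passed over all genes or over the list alone. Members past the threshold were counted in the fit without the replicate block only, for this and the other lists, so members could pass in the blocked fit. With the replicate block, replication-dependent histones (median −0.14) and glycolysis and hypoxia genes (median −0.16) also passed as lower (adjusted p = 0.00387 and adjusted p = 0.0131). None of these 6 lists passed with an estimated correlation (adjusted p = 0.991 for each, without the block). Single members of other lists that fell included the BET protein Brd2 (−0.53 ± 0.10), the Polycomb subunit L3mbtl2 (−0.79 ± 0.14), the INO80 subunit Actr5 (−0.57 ± 0.09), the mitochondrial tryptophanyl-tRNA synthetase Wars2 (−1.60 ± 0.12), the splicing factors Tra2b (−0.80 ± 0.13) and Rbm39 (−0.74 ± 0.11), and Atf4, a transcription factor of the integrated stress response (−0.97 ± 0.25). The INO80 subunit Actr8 (0.50 ± 0.09), the cohesin subunit Rad21 (0.34 ± 0.07) and the cystine transporter Slc7a11 (1.10 ± 0.18) rose.

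The same replicate numbers pair the TT-seq libraries, and all 1032 calls remained with the number as a block. With library sizes taken from the Drosophila spike-in no gene passed in edgeR, the only tool run with these sizes (67 genes at an unadjusted p under 0.05). With spike-in sizes and the block 806 were higher and 1930 lower (29.5% higher), again with all 1032. Leaving out a library reduced the higher calls to 89, 104 and 56 (untreated replicates 1, 2 and 3) and to 133 and 54 (auxin replicates 2 and 3). The lower calls fell to 375 and 379 (untreated and auxin replicate 3). Without replicate 1 of both groups, which had the largest share of counts on the ribosomal precursor Rn45s (35.4% and 38.8%), 70 were higher and 467 lower.

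Total labelled RNA per spike-in count was close before and after auxin relative to the spread between replicates. Mouse gene counts per Drosophila gene count were 43.1, 115 and 69.4 in untreated replicates 1, 2 and 3 and 43.1, 99.3 and 63.8 in the auxin replicates. The difference of the mean log2 ratios was −0.11 (two-sided exact permutation test, p = 0.7, where 0.1 is the smallest that 3 against 3 can give). Within the pairs it was 0, −0.21 and −0.12 (exact sign-flip permutation test, p = 0.25, also the smallest possible). Leaving out single libraries moved the difference between −0.46 and 0.25, but this breaks a pair and so takes in the spread between the replicate numbers. Without the ribosomal precursor Rn45s the ratios were 27.8, 89.2 and 50.7 in untreated replicates 1, 2 and 3. They were 26.3, 76.1 and 48.1 in the auxin replicates, lower in each pair, and this difference was not tested.

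Steady-state RNA at 4 h of auxin showed smaller changes, in genes close to those of TT-seq. In RNA-seq, 476 genes were higher and 627 lower (edgeR, adjusted p under 0.05, 15157 tested), 42 and 58 of them by more than 1 on the log2 scale. Cyb5d2 (1.84 ± 0.08) and Thap1 (1.39 ± 0.07) rose most, followed by the thrombin receptor gene F2rl2 (1.25 ± 0.30), Tyw3 (0.95 ± 0.13), Tagap1 (0.90 ± 0.11) and the minor spliceosome component Snrnp35 (0.89 ± 0.08). Plod2, a lysyl hydroxylase of collagen (−1.62 ± 0.46), the branched-chain amino acid enzyme Dbt (−1.30 ± 0.15), Tmtc2 (−1.29 ± 0.28), Prob1 (−1.28 ± 0.17) and Zfp827 (−1.24 ± 0.18) were among the genes that fell most. Each difference is of 3 libraries against 3.

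Cholesterol biosynthesis stood out among the lists at 4 h, with 10 of 23 genes higher and none lower (15 and none adjusted over the list alone, median 0.28, camera adjusted p = 2.61e-10), including Msmo1 (0.49 ± 0.09), Mvd (0.47 ± 0.10) and Sc5d (0.41 ± 0.07). Targets of p53 were higher (5 of 27, 6 adjusted over the list alone, adjusted p = 0.0113), led by Plk3 (0.68 ± 0.11) and the DNA repair nuclease Ercc5 (0.36 ± 0.07). The others that passed included Ckap2 (0.29 ± 0.06) and Gtse1 (0.33 ± 0.08), which are also mitotic genes. Glycolysis and hypoxia genes were lower as a list (median −0.42, adjusted p = 1.12e-05), with hexokinase 1 (Hk1, −0.27 ± 0.05) the only member of 26 to pass over all genes, and 1 higher and 7 lower adjusted over the list alone. The 0 h libraries themselves spread widely for this list, with medians of 0.22, 0.88 and 0.51 in centred log2 CPM. Oxidative phosphorylation was also lower (median −0.05, adjusted p = 0.0424) without any member passing over all genes or the list alone. None of these calls held with an estimated correlation (adjusted p = 0.986 for each). Members of other lists that fell included Brd2 (−0.52 ± 0.05), L3mbtl2 (−0.47 ± 0.06), Tra2b (−0.41 ± 0.05), Srsf3 (−0.45 ± 0.06), Mrps18b (−0.46 ± 0.08), the histone chaperone Nasp (−0.36 ± 0.07) and Atf4 (−0.48 ± 0.10). Those that rose included Actr8 (0.44 ± 0.06), Ino80 (0.59 ± 0.09), Ino80b (0.60 ± 0.10) and Utp20 (0.48 ± 0.06). DESeq2 called 1050 lower genes in place of 627. Leaving out 1 library reduced the higher calls to 215, 206 and 240 (0 h replicates 1, 2 and 3) and 248, 215 and 227 (4 h replicates 1, 2 and 3). The lower calls fell to 397 (without 0 h replicate 2) and 414 (without 4 h replicate 3).

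Changes of nascent and steady-state RNA at 4 h went together across the 10110 genes tested in both, with Pearson r = 0.57 and Spearman rho = 0.63 (7152 genes with mean log2 CPM of at least 3 in both gave r = 0.73). TT-seq values here are from the fit without the replicate block. The blocked fit, with 5374 calls against 1032, was not compared with RNA-seq. Of the genes that fell in TT-seq without the block, 371 of 773 also fell in RNA-seq, where independent lists would share 45.9 (odds ratio 36.7, Fisher's exact test, p = 2.82e-291). Of those that rose, 75 of 220 also rose, against 9.1 (odds ratio 14.4, Fisher's exact test, p = 1.45e-49). Ttc27, Brd2 and L3mbtl2 were among the genes lower in both, and Thap1 and Cyb5d2 among those higher in both. With later RNA-seq, 635 of the 773 fell at 24 h and 592 at 48 h, where independent lists would share 224.9 and 250.7. Genes are not independent replicates, and no library enters both assays.

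**Figure D2:**
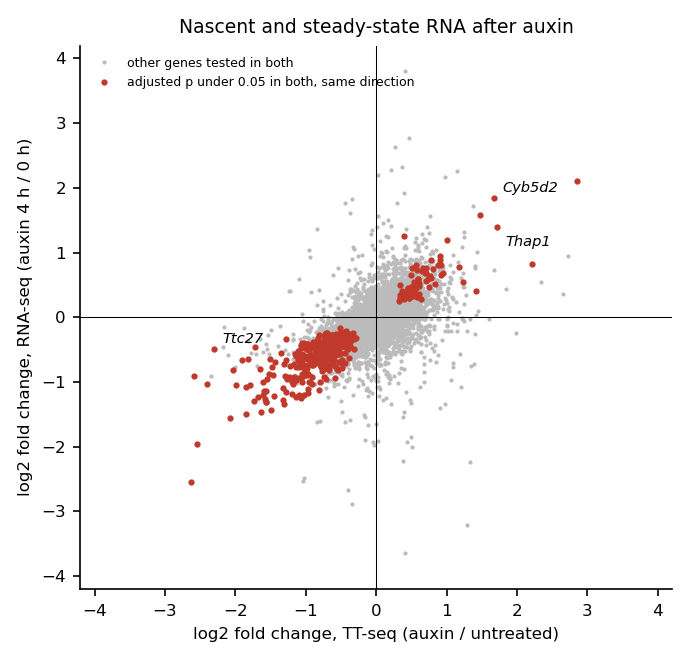
Log2 fold change in RNA-seq (4 h against 0 h of auxin, vertical) against TT-seq (auxin against untreated, horizontal) for the 10110 genes tested in both; 1 gene lies outside the axes. Red points, 75 in the upper right and 371 in the lower left, passed an adjusted p of 0.05 in both assays in the same direction. TT-seq was fitted without the replicate block.

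By 24 h of auxin 3253 genes were higher and 3258 lower in RNA-seq (edgeR, adjusted p under 0.05, 15157 tested), 1125 and 462 of them by more than 1 on the log2 scale. The time series has no untreated libraries besides those at 0 h. Changes at 24 and 48 h, of genes and of lists, may therefore include effects of time in culture, which were not separated from the loss of YY1. The largest gains were Spata31f1a (4.62 ± 0.13), the platelet glycoprotein Gp9 (2.90 ± 0.19), F2rl2 (2.37 ± 0.29), the red cell anion exchanger Slc4a1 (2.30 ± 0.26), the meiotic mismatch repair gene Msh5 (2.2 ± 0.2) and Syngr4 (2.10 ± 0.10). The largest losses were the mitochondrial proteins Nipsnap1 (−4.35 ± 0.21), Clybl (−3.80 ± 0.29) and Chchd10 (−3.41 ± 0.23), together with Cand2 (−3.47 ± 0.19), the Polycomb-related Sfmbt2 (−3.21 ± 0.11) and Ttc27 (−3.05 ± 0.15), each with 3 libraries per group.

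Ribosome biogenesis fell at 24 h in 42 of 46 genes (43 adjusted over the list alone, median −0.48, camera adjusted p = 5.56e-16), among them nucleolin (Ncl, −0.78 ± 0.07), Noc2l (−0.78 ± 0.06) and Nolc1 (−0.88 ± 0.08), and 1 gene rose. This list and the other 14 that passed at 24 h did not pass with an estimated correlation (adjusted p = 0.416 to 0.622). Cholesterol biosynthesis, higher at 4 h, now fell in 22 of 23 genes (all 23 adjusted over the list alone, median −0.68, adjusted p = 2.79e-12), with Idi1 at −0.86 ± 0.07 and Mvd at −1.02 ± 0.10. Oxidative phosphorylation fell in 39 of 77 genes and rose in 2 (40 and 3 adjusted over the list alone, adjusted p = 4.04e-07), with Ndufc1 at −1.28 ± 0.09 and Uqcrc1 at −0.97 ± 0.07. Mitochondrial ribosomal proteins fell in 32 of 77 and rose in 9 (32 and 10 adjusted over the list alone, adjusted p = 0.00143), with Mrps18b at −1.33 ± 0.08. Glycolysis and hypoxia genes fell in 17 of 26 (17 also over the list alone, adjusted p = 1.59e-05), with Hk1 at −0.93 ± 0.05 and enolase (Eno1) at −1.35 ± 0.22. The 24 h libraries differed for this list, with medians of −0.61, −0.61 and 0.27 in centred log2 CPM, the last above 0 h replicate 1 (0.22). S phase genes fell in 21 of 45 and rose in 4 (22 and 5 adjusted over the list alone, adjusted p = 0.00281), with Nasp at −1.25 ± 0.07 and the replication helicase subunit Mcm5 at −0.88 ± 0.06. Genes also fell among heat shock genes (11 of 17, adjusted p = 0.000185), splicing factors (23 of 51, adjusted p = 9.46e-05), aminoacyl tRNA synthetases (19 of 40, adjusted p = 0.00302), proteasome subunits (17 of 41, adjusted p = 0.00407), the integrated stress response (14 of 28, adjusted p = 0.00957), stem and progenitor regulators (7 of 16, adjusted p = 0.0438) and replication-dependent histones (5 of 29, adjusted p = 0.0438), with 12, 23, 20, 17, 14, 7 and 1 lower adjusted over the list alone. Over all genes 3258 of 15157 were lower, a larger share than the 5 of 29 histones, so that list did not stand out by its called members. Myc (−0.91 ± 0.07), Ikzf1 (−1.12 ± 0.07) and Gata2 (−0.86 ± 0.09) were among the progenitor regulators that fell.

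Targets of p53 rose in 18 of 27 genes at 24 h and fell in 1 (21 and 1 adjusted over the list alone, adjusted p = 6.61e-07), with Eda2r at 1.36 ± 0.09, the pro-apoptotic Bbc3 at 1.07 ± 0.09 and Ccng1 at 0.66 ± 0.05. Megakaryocyte markers rose in 5 of 12 (5 also over the list alone, adjusted p = 0.0255), with the integrin Itga2b at 1.69 ± 0.13 besides Gp9 and F2rl2. Neither the p53 nor the megakaryocyte list passed with an estimated correlation. The erythroid program went both ways, with 8 of 39 genes higher and 14 lower (9 and 15 adjusted over the list alone), and did not pass as a list (adjusted p = 0.161). Slc4a1 was among those that rose, and carbonic anhydrase 1 (Car1, −1.26 ± 0.13) and Lmo2 (−0.66 ± 0.05) fell. Heme and iron genes likewise did not pass as a list (4 of 24 higher, 11 lower, adjusted p = 0.0889), although Steap3 (−1.05 ± 0.08) and Cpox (−0.76 ± 0.09) fell. Of the markers of other cell types, myeloid markers had 1 of 8 higher and 2 lower (adjusted p = 0.531), mast cell markers 1 of 8 higher and 2 lower (adjusted p = 0.563), and lymphoid markers, too few to test, 2 of 4 lower (Lck and Cd3g).

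At 48 h 3777 genes were higher and 3733 lower in RNA-seq (edgeR), 1447 and 637 of them by more than 1 on the log2 scale. Spata31f1a (5.10 ± 0.13), F2rl2 (3.77 ± 0.29), Gp9 (3.62 ± 0.19), Slc4a1 (2.85 ± 0.26), Itga2b (2.71 ± 0.13) and the lipid transfer gene Mttp (2.59 ± 0.10) rose most. Nipsnap1 (−6.14 ± 0.25), Cand2 (−4.35 ± 0.21), Clybl (−3.80 ± 0.29), the membrane metalloproteinase Mmp14 (−3.66 ± 0.18), Chchd10 (−3.60 ± 0.23) and Sfmbt2 (−3.27 ± 0.11) fell most. Ribosome biogenesis was lower in 44 of 46 genes (44 also over the list alone, camera adjusted p = 6.5e-18), oxidative phosphorylation in 56 of 77 (58 adjusted over the list alone, adjusted p = 5.88e-11), mitochondrial ribosomal proteins in 47 of 77 (49, adjusted p = 5.43e-08) and the proteasome in 32 of 41 (32, adjusted p = 7.05e-07). S phase genes were lower in 28 of 45 (31 adjusted over the list alone, adjusted p = 6.24e-07), splicing factors in 30 of 51 (31, adjusted p = 9.8e-07), cholesterol biosynthesis in 18 of 23 (21, adjusted p = 2.87e-06) and aminoacyl tRNA synthetases in 23 of 40 (23, adjusted p = 2.93e-05), where Wars2 stood at −2.92 ± 0.21. Megakaryocyte markers were higher in 8 of 12 (8 also over the list alone, median 1.19, adjusted p = 0.000265), with Itgb3 at 1.15 ± 0.08, p53 targets in 18 of 27 (19, adjusted p = 3.02e-06) and interferon response genes in 11 of 19 (11, adjusted p = 0.0136), among them Parp14 (0.82 ± 0.13). The erythroid program again went both ways (11 of 39 higher, 12 lower, adjusted p = 0.905), with Car1 at −2.60 ± 0.14. The 15 lists past the threshold at 48 h had adjusted p = 0.304 to 0.8 with an estimated correlation.

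**Figure D3:**
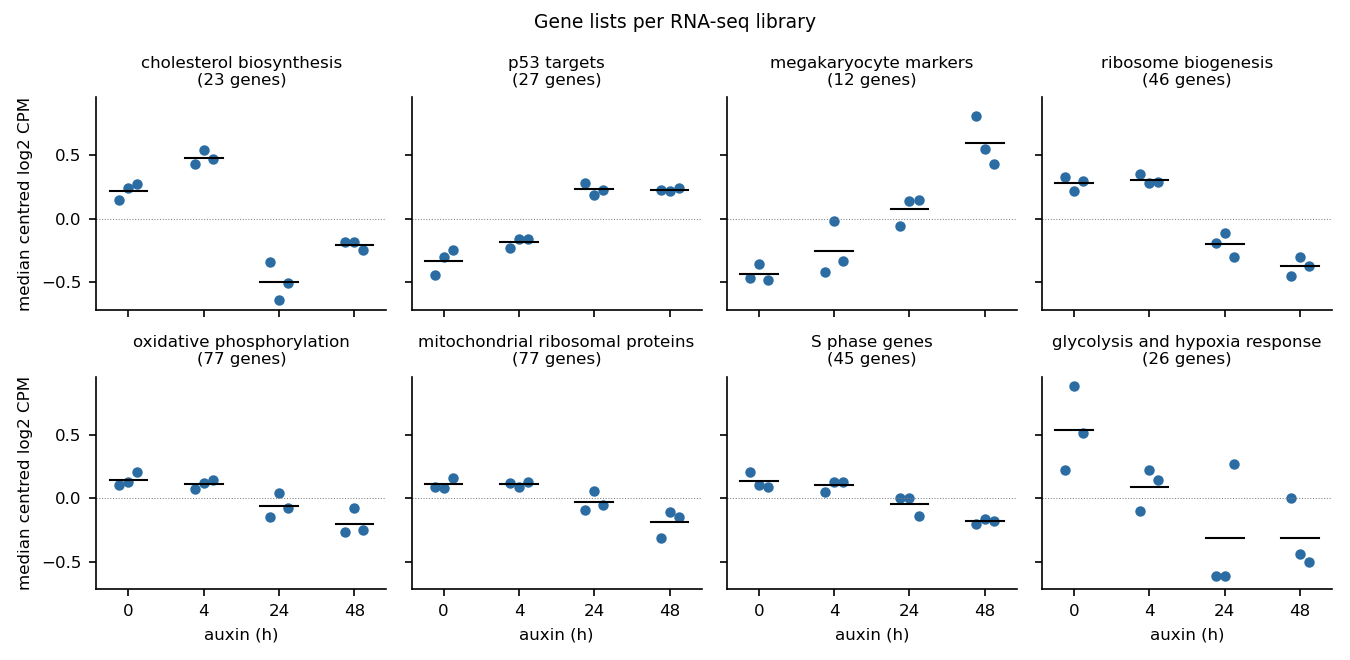
Median over the members of 8 gene lists of log2 CPM centred per gene, in each of the 12 RNA-seq libraries (points, 3 per time of auxin) with the mean of the 3 as a bar. Cholesterol biosynthesis genes lay highest at 4 h and lowest at 24 h, and the 0 h libraries of the glycolysis and hypoxia list spread from 0.22 to 0.88.

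Testing the time points against each other located most of the change between 4 and 24 h. From 4 to 24 h, 2408 genes rose and 2685 fell (edgeR), 785 and 236 by more than 1 on the log2 scale, led by Spata31f1a (3.87 ± 0.12), Nedd4l (2.53 ± 0.74), Gp9 (2.50 ± 0.18) and Slc4a1 (2.33 ± 0.26) upward and Nipsnap1 (−3.80 ± 0.21), Clybl (−3.43 ± 0.29), Chchd10 (−3.07 ± 0.23) and Ttc27 (−2.56 ± 0.15) downward. All 23 cholesterol biosynthesis genes fell in this interval (23 also over the list alone, median −0.98, camera adjusted p = 8.08e-21, and adjusted p = 0.323 with an estimated correlation), as did 44 of 46 ribosome biogenesis genes (44 also over the list alone, adjusted p = 1.1e-21, 0.323 with an estimated correlation). From 24 to 48 h, 459 genes rose and 430 fell, with F2rl2 (1.40 ± 0.25), Cuedc1 (1.36 ± 0.20), Gsn (1.35 ± 0.20) and Inpp4b (1.34 ± 0.26) up and Nipsnap1 (−1.79 ± 0.31), Tmem44 (−1.54 ± 0.23), Slc30a2 (−1.37 ± 0.14) and Car1 (−1.34 ± 0.13) down. Megakaryocyte markers rose in 7 of 12 (7 also over the list alone, adjusted p = 5.78e-08, and adjusted p = 0.0393 with an estimated correlation), S phase genes fell in 12 of 45 (21 adjusted over the list alone, adjusted p = 1.61e-10), and cholesterol biosynthesis genes rose again in 9 of 23 (13 adjusted over the list alone, adjusted p = 8.2e-09), the last 2 with adjusted p = 0.301 with an estimated correlation. DESeq2 called 778 and 686 genes in this last interval. Without 1 library the higher calls came to 297 and 213 (24 h replicates 1 and 2) and 217 and 249 (48 h replicates 1 and 2). The lower calls came to 182 (24 h replicate 2), 164 and 257 (48 h replicates 1 and 3).

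Genes changed at 4 h were mostly changed the same way later. Of 476 genes higher at 4 h, 312 were higher at 24 h and 308 at 48 h, and of 627 lower, 526 and 480 were lower, where independent lists would share 102.2, 118.6, 134.8 and 154.4. Between 24 and 48 h, 2764 higher and 2785 lower genes were shared. In 20 simulations of unchanged groups against the same 0 h libraries no calls were shared, which follows from simulating no change and is no measure of agreement. Fold changes at 4 and 24 h correlated across genes with r = 0.50 against 0.51 in these simulations, because the comparisons share their controls, but their covariance was 0.216 against 0.0641. At 24 and 48 h the covariance was 0.618 against 0.0631 (r = 0.85 against 0.50), and at 4 and 48 h it was 0.221 against 0.0627 (r = 0.46 against 0.50). With 3 control libraries the controls could not be split into parts of at least 2, so part of the shared calls may come from the shared controls.

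Calls of single genes between untreated YY1-AID and parental cells depended on the tool, the filter and the replicate block. No gene passed in the YY1-AID subline or in subline 3 against parental cells with edgeR (557 and 534 of 10892 genes at an unadjusted p under 0.05) or with voom. Without a filter on low counts edgeR called 7 higher and 27 lower in the subline and 1 higher in subline 3. DESeq2 called 64 higher and 137 lower in the subline and 101 higher and 56 lower in subline 3. The first principal component, 48.2% of the variance, separated the replicate numbers. On it replicate 1 of parental cells, the subline and subline 3 lay at −42, −49.7 and 1.55, and replicate 2 at 27.6, 18.6 and 44. Replicate 1 of subline 3 thus lay apart from the other libraries of its number. With the number as a block 177 were higher and 261 lower in the subline and 457 and 223 in subline 3. The erythroid program had medians of 0.29 and 0.47 over 40 genes (camera adjusted p = 6.81e-09 and adjusted p = 1.18e-11, and adjusted p = 0.13 and 0.0877 with an estimated correlation), with 6 and 8 genes higher adjusted over the list alone and none over all genes. Megakaryocyte markers were also higher as a list (median 1.15 in each, adjusted p = 0.000129 and adjusted p = 2.33e-07, and 0.246 and 0.182 with an estimated correlation; 5 higher and 1 lower adjusted over the list alone in each). Mast cell markers were lower (medians −0.91 and −0.36 over 7 genes, adjusted p = 0.000129 and adjusted p = 0.0272, and 0.256 and 0.641 with an estimated correlation), with 2 lower in each and 1 higher in subline 3 adjusted over the list alone. Myeloid markers went down in the subline (median −0.20, adjusted p = 0.108) and up in subline 3 (median 0.28, adjusted p = 0.00374, and 0.641 with an estimated correlation). In all, 5 and 13 of 26 lists passed, and none did with an estimated correlation. List values in this paragraph are from the fit without the block, and with the block 8 and 16 lists passed. Cytosolic ribosomal proteins were lower in subline 3 (median −0.31, adjusted p = 5.75e-05, and 0.733 with an estimated correlation) without any gene passing over all genes or over the list alone. In simulated counts with the spread of these 2 libraries per group, the fit without the block recovered none of 200 genes changed by 1 on the log2 scale. The batch entered that spread as noise, so this does not speak to the blocked fit.

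Subline 3 and the YY1-AID subline differed in 9 genes, all higher in subline 3 with edgeR and none lower (572 at an unadjusted p under 0.05; voom called 22 higher, DESeq2 168 higher and 41 lower, and the blocked fit 483 and 190). They included 4 genes of leukocyte signalling and the actin cytoskeleton. Nckap1l stood at 10.1, 0.062 and 76.0 CPM in parental cells, the subline and subline 3, Dock2 at 11.9, 0.136 and 80.5, Hcls1 at 3.5, 0.68 and 43.5, and Pik3cg at 2.29, 0.261 and 31.5. In the subline these rest on 1 and 4 counts for Nckap1l, 5 and 6 for Dock2, 28 and 27 for Hcls1 and 7 and 14 for Pik3cg. Leaving out a library leaves 1 in its group and less power: none passed without either library of subline 3, and 1 (Nckap1l) without either library of the subline. The log2 fold changes stayed large, at 9.52 to 11.43 for Nckap1l (10.19 ± 0.47 with all libraries) and 8.94 to 9.41 for Dock2 (9.18 ± 0.46).

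YY1 peaks of asynchronous cells titled as CTCF-AID were mostly kept after 4 h of auxin. There were 16355 untreated and 20074 auxin peaks, 83.5% of the former were retained (Wilson 95% interval 82.9 to 84.0) and 68.0% of the latter had an untreated counterpart. Lost YY1 peaks overlapped CTCF peaks slightly more often than kept ones (18.4% against 16.4%, odds ratio 1.15, Fisher's exact test across peaks, p = 0.013), and peaks gained with auxin did so in 10.4%. The genotype label of these samples reads YY1-AID while the title names CTCF-AID. The retained share of 83.5%, against 7.55% in the YY1-AID cells above, goes against a loss of YY1 like the one there, and whether CTCF was depleted was not tested.

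YY1 peaks of G1E-ER4 cells synchronised with 7 h of nocodazole and purified by FACS were listed by the authors as emergent at 1 of 5 stages from mitosis to G1, and most were listed for early G1. Of 19683 peaks, 681 (3.46%) were listed for prometaphase, 5713 (29.0%) for ana/telophase, 10643 (54.1%) for early G1, 2403 (12.2%) for mid-G1 and 243 (1.23%) for late G1. H3K27ac of asynchronous cells lay at 91.0%, 80.7%, 54.6%, 51.9% and 37.4% of these peaks in that order, and LDB1 at 3.82%, 12.6%, 17.9%, 23.1% and 22.2%. CTCF lay at 19.7%, 19.7%, 14%, 16.2% and 10.7%, and RAD21 at 27%, 25.5%, 19.8%, 24.3% and 16.9%. Prometaphase and early G1 lists differed in H3K27ac (odds ratio 8.45, adjusted p = 1.43e-90 over 40 Fisher's exact tests across peaks), LDB1 (odds ratio 0.182, p = 2.53e-27), CTCF (odds ratio 1.51, p = 0.000133) and RAD21 (odds ratio 1.5, p = 2.46e-05). The CTCF and RAD21 differences did not pass with overlaps of at least 50% of the smaller peak (10.6% against 10%, adjusted p = 0.738, and 14.8% against 14.3%, adjusted p = 0.77). With peaks reduced to 200 bp H3K27ac lay at 27%, 22%, 12.6%, 15.1% and 13.2% of the lists, so its share then did not fall steadily, and prometaphase still differed from early G1 (odds ratio 2.56, adjusted p = 3.21e-21). Mid-G1 and late G1 did not differ in LDB1 (adjusted p = 0.832), where the late G1 list is short. Every overlap exceeded 200 random shifts of the peaks (permutation by shifting, p = 0.005, the smallest possible). Of the same lists, 97.8%, 34.7%, 8.11%, 2.79% and 7.0% were still YY1 peaks after auxin in asynchronous YY1-AID cells. Before auxin 98.4%, 87.6%, 63.9%, 70.2% and 43.6% were YY1 peaks there. The occupancy of the other proteins comes from asynchronous cells, not from the stage itself.

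**Figure D4:**
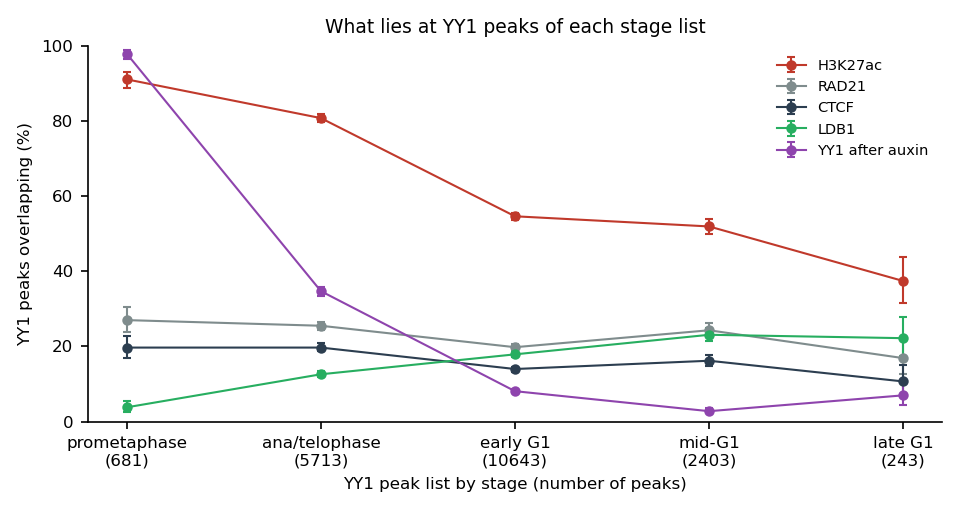
Share (%) of YY1 peaks in each stage list that overlap a peak of H3K27ac, RAD21, CTCF or LDB1 in asynchronous untreated YY1-AID cells, or a YY1 peak after auxin; bars are Wilson 95% intervals. H3K27ac falls from 91.0% to 37.4% (27% to 13.2% with peaks reduced to 200 bp, without a steady fall), peaks still called after auxin go from 97.8% to 7.0%, lowest in mid-G1 (2.79%), and LDB1 from 3.82% to 22.2%, highest in mid-G1 (23.1%).

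Similar shares of asynchronous and mid-G1 Micro-C loops had a YY1 peak of asynchronous cells at both anchors. All peaks used here come from asynchronous untreated YY1-AID cells, so the shares do not measure binding in mid-G1 itself. The merged lists held 12738 loops in asynchronous and 14155 in mid-G1 cells. YY1 peaks lay at both anchors of 24.5% and 24.6%, at 1 anchor of 32.7% and 33.8% and at neither of 42.8% and 41.5%. CTCF lay at both anchors of 63.6% and 65.8%, RAD21 of 62.3% and 64.9%, H3K27ac of 20.4% and 20.5%, and LDB1 of 4.84% and 5.64%. After random shifts of the peaks YY1 lay at both anchors of 1.92% and 2.11% (permutation by shifting, p = 0.005, the smallest that 200 shifts can give). Loops with YY1 at both anchors spanned a median of 150 kb at each stage against 190 and 195 kb for loops without YY1. They had H3K27ac at both anchors in 68.6% and 67.5%, against 0.734% and 0.731%. Of all asynchronous loops, 12.7% had YY1 with CTCF and RAD21 at both anchors and 11.8% had YY1 without that pair. Of the latter 84.0% had H3K27ac at both anchors. Between stages 44.4% of asynchronous loops were found in mid-G1, less often for loops with YY1 at both anchors than for others (41.2% against 45.4%, odds ratio 0.842, Fisher's exact test across loops, p = 3.72e-05). With only YY1 peaks that the second antibody also found, 5.21% and 5.04% of loops had YY1 at both anchors, and with anchors widened by 5 kb on each side 39.5% at each stage. The lists merge untreated and auxin samples, so loops lost or gained with auxin cannot be read from them.

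**Figure D5:**
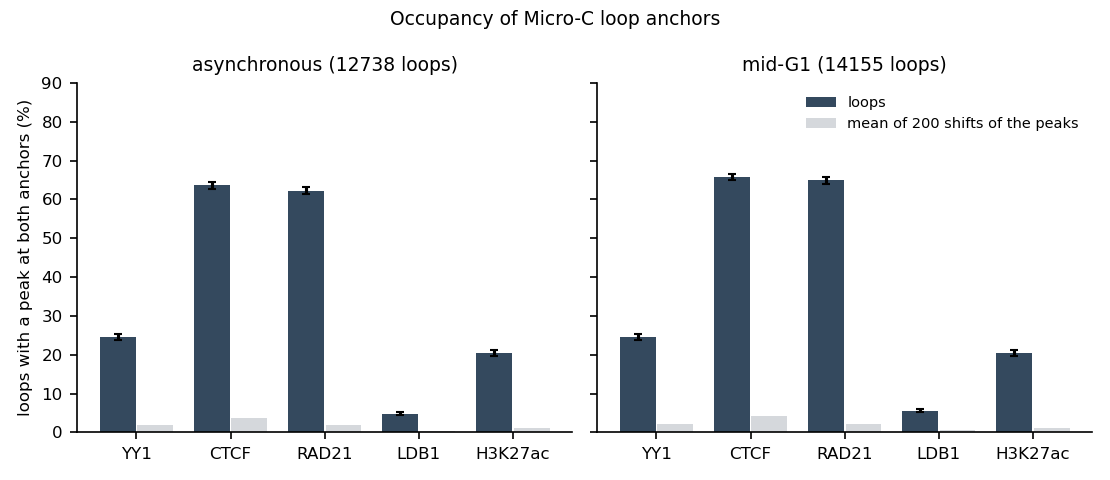
Share (%) of Micro-C loops with a peak of each protein or mark at both anchors (dark bars, Wilson 95% intervals) and the mean over 200 random shifts of the peaks (light bars), for 12738 asynchronous and 14155 mid-G1 loops. CTCF and RAD21 lie at over 60% of loops and YY1 at 24.5% and 24.6%. Peaks of asynchronous untreated YY1-AID cells were used for both stages.

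Contact domains were mostly called in both untreated and auxin cells. In asynchronous cells 3414 of 5990 domains (57.0%) were marked by the authors as called in both, 1307 in untreated cells alone and 1269 in auxin cells alone. In mid-G1 the numbers were 2842 of 4836 (58.8%), 969 and 1025. Median domain size was 300 kb in asynchronous and 260 kb in mid-G1 cells. CTCF lay at 41.7% of 6070 asynchronous and 42.6% of 5508 mid-G1 boundaries (18.5% and 18.6% after shifts), RAD21 at 32.6% and 34.0%, YY1 at 22.6% and 24.4% (12.2% in each after shifts), H3K27ac at 15.8% and 17.5%, and LDB1 at 7.76% and 8.22%. Each share exceeded all 200 shifts (permutation by shifting, p = 0.005). Peaks of asynchronous untreated cells were used for both stages, so binding at boundaries in mid-G1 itself was not measured. Widening each boundary by 10 kb on each side raised YY1 to 42.5% and 45.7%, because more sequence is searched. Of asynchronous boundaries 38.3% were found in mid-G1, and of mid-G1 boundaries 42.2% in asynchronous cells.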

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

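The tests on the cholesterol genes, on the spread of the 0 h libraries and of other splits of the libraries were chosen after the results were seen.

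Cholesterol biosynthesis genes moved in opposite directions at 4 and 24 h of auxin, and the difference between these times was tested directly: all 23 members were lower at 24 h than at 4 h. A single deviating 0 h library is argued against as the whole source: with each 0 h library left out in turn the list's median was at least 0.23 at 4 h and at most −0.67 at 24 h. A deviation of all 3 together was not tested. Scaling between libraries is also argued against, since another scaling or centring moved the list's median by at most 0.03, against medians of 0.28 at 4 h and −0.68 at 24 h. Culture conditions at collection, such as density or medium, stay open: 87.5% of the members measured in TT-seq at 4 h (21 of 24) lay above 0, which a change in the culture shared by both experiments could also give. A response to the loss of YY1 stays open too, and no sample treated with auxin without the degron is analysed here.

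Single genes also changed direction over time. Of 882 genes past the threshold at both 4 and 24 h, 44 went in opposite directions, 38 of them higher and then lower, and all 44 differed between the times, as genes picked in this way almost must. Between 24 and 48 h, 13 of 5562 did so, 3 of them higher and then lower, and all 13 differed, for the same reason. Between 4 and 48 h, 66 of 854 did so, where the difference was not tested.

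YY1 peaks kept after auxin came mostly from the prometaphase and ana/telophase lists, 2596 of 3108 (83.5%, Wilson 95% interval 82.2 to 84.8) against 13.8% of all untreated YY1 peaks. Of the 41163 untreated peaks, 5671 were in these mitotic lists, 8526 in the G1 lists and the others in no stage list. Only 54 kept peaks (1.74%) were in no stage list, so those untreated peaks were kept least often and lower the 13.8%. Kept shares were 45.8% of peaks from the mitotic lists and 5.37% of those from the G1 lists (odds ratio 14.9). Detection by the second antibody alone is argued against as the whole source, since among peaks with that antibody the odds ratio was 17.5, and without it 3.65. Location in acetylated regions alone is argued against likewise, with an odds ratio of 23.2 among peaks with H3K27ac and 3.94 among those without. Finer differences in peak strength stay open, because the lists hold no score, and strong peaks may remain above a threshold after partial depletion.

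Glycolysis and hypoxia genes were lower at 4 h, but the 0 h libraries differed widely among themselves. The list's median of −0.42 became −0.30 without 0 h replicate 2 and −0.58 without 0 h replicate 1. Whether the spread between the 0 h libraries is the source cannot be told apart from an effect of auxin with 3 libraries per time. In the separate TT-seq libraries the list was also lower after auxin in each pair (0.16 to 0.05, 0.05 to −0.22 and −0.01 to −0.07 in centred log2 CPM). As a list it passed there with the replicate block (median −0.16, camera adjusted p = 0.0131) and not without it (adjusted p = 0.0688). With an estimated correlation, without the block, it did not pass either (camera adjusted p = 0.991). The RNA-seq 0 h libraries cannot produce that decrease, which is smaller, so their part in the RNA-seq change stays open, and no biological explanation was tested.

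Other splits of the same 6 libraries into 3 against 3 gave fewer calls in each comparison, where 1 of 10 splits, the real one, gave as many. The real and highest other counts were 1103 and 0 for RNA-seq at 4 h, 6511 and 0 at 24 h, 7510 and 0 at 48 h, 5093 and 0 for 24 against 4 h, 889 and 2 for 48 against 24 h, and 1032 and 0 for TT-seq, where the 4 splits that part every pair included no other with a call. These splits are too few for a share under 0.05. Every other split also mixes both conditions within each group, so a real difference widens the spread and lowers the calls by construction. Their low counts are therefore no measure of how many calls chance would give.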

How the results depend on the processing

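The fit of TT-seq without replicate 1 of both groups and the tests between stages under stricter overlaps were chosen after the data were seen, and the other alternatives were planned.

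Under the alternatives run, 175 counts of calls stayed within 1.5 times the reported count and 69 moved further. Of the values for named genes 1712 kept their direction and side of the threshold, 100 kept their direction without passing, 1 passed newly and 2 changed direction: Yy1 at 48 h, not called, came to −0.02 without 48 h replicate 2 and to −0.02 without 0 h replicate 3, with 0.09 the highest. List results under an estimated correlation kept 139 calls or non-calls and lost 94 calls. With fry 181 stayed, 36 were lost and 16 gained, and with the replicate block 219 stayed, 3 were lost and 11 gained. The cause was not tested where no reason is given.

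Asking for an absolute log2 fold change of at least 1 lowers counts by construction, to 42 higher and 58 lower in RNA-seq at 4 h, 1125 and 462 at 24 h, 1447 and 637 at 48 h, 785 and 236 for 24 against 4 h, 61 and 39 for 48 against 24 h, and 49 and 136 in TT-seq. DESeq2 called 1050 lower at 4 h, 778 higher and 686 lower for 48 against 24 h, 64 and 137 in the YY1-AID subline, 101 and 56 in subline 3, and 168 and 41 between the sublines. Without a filter on low counts 7 were higher and 27 lower in the subline, 1 was higher in subline 3, and 28 and 2 differed between the sublines, where voom called 22 higher. With only the 2 groups in the fit 161 were lower for 48 against 24 h and 3 higher between the sublines, with fewer samples to estimate the spread.

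With the replicate block 177 were higher and 261 lower in the subline, 457 and 223 in subline 3, 483 and 190 between the sublines, and 2541 and 2833 in TT-seq. With spike-in library sizes TT-seq gave 0 and 0 in edgeR (67 genes at an unadjusted p under 0.05), and 806 and 1930 with spike-in sizes and the block. In the time series correlations between libraries of the same number were −0.07 to 0.10. For 4 h against 0 h and 48 h against 24 h every library correlated best with its own number, a weak hint of pairing, and for the other comparisons not every library did. The block gave 1493 calls at 4 h, 1088 of the 1103 among them, and 6894 at 24 h.

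Leaving out 1 library gave 206 to 248 higher and 397 to 483 lower at 4 h, 213 to 352 higher and 164 to 375 lower for 48 against 24 h, and 0 to 1 higher between the sublines, where a lone library is assumed to vary like the other groups. In TT-seq it gave 54 to 172 higher and 375 to 701 lower, and without replicate 1 of both groups 70 and 467. Fewer libraries leave less power in each of these. The spike-in difference of −0.11 turned to 0.19 without auxin replicate 1 and to 0.25 without untreated replicate 2, and its lowest value was −0.46.

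Retained shares of CTCF, RAD21 and LDB1 were the same with overlaps of at least 50% of the smaller peak and with peaks reduced to 200 bp. They came to 95.4% for CTCF at YY1 peaks, 92.8% for RAD21 at YY1 peaks and 85.2% for LDB1 away from YY1. Lost YY1 peaks of the CTCF-AID-titled cells overlapped CTCF in 13.7% under both settings. Kept YY1 peaks there did so in 10.0% and 9.94%, a wider difference than in the main setting (odds ratios 1.43 and 1.44 against 1.15). For H3K27ac the first setting gave 90.6% in all, 98.4% at YY1 peaks and 76.6% elsewhere, and the second 67.0%, 77.0% and 63.4%, since wide peaks have shifting midpoints.

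In the prometaphase, ana/telophase, early, mid- and late G1 lists of YY1 peaks, H3K27ac shares with 200 bp peaks were 27%, 22%, 12.6%, 15.1% and 13.2%. With overlaps of at least 50% they were 77.9%, 51.8% and 47.9% in ana/telophase, early and mid-G1. In the first 4 lists, CTCF came to 10.6%, 13.1%, 10% and 13% with the 50% overlap and to 10.6%, 13%, 10% and 13% with 200 bp peaks. RAD21 came to 14.8%, 17.2%, 14.3% and 19.3%, and to 14.8%, 17.2%, 14.2% and 19.3%. LDB1 in ana/telophase, early and mid-G1 came to 9.31%, 13.1% and 19% and to 9.19%, 13% and 19%.

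Widening loop anchors by 5 kb searches more sequence and raised the shares with both anchors occupied to 39.5% for YY1, 81.4% for CTCF, 79.5% for RAD21, 11.5% for LDB1 and 29.5% for H3K27ac in asynchronous cells, and to 39.5%, 82.3%, 80.6%, 12.3% and 29.4% in mid-G1. Shared loops rose to 69.4% and 62.6%. With YY1 peaks supported by the second antibody the YY1 shares were 5.21% and 5.04%. Widening boundaries by 10 kb raised YY1, CTCF, RAD21, LDB1 and H3K27ac to 42.5%, 67.4%, 59.3%, 18.3% and 30.6% in asynchronous cells and to 45.7%, 69.4%, 61.2%, 20.4% and 33.7% in mid-G1, and shared boundaries to 57.5% and 62.9%. The correlation of TT-seq with RNA-seq at 4 h was 0.73 over genes with a mean log2 CPM of at least 3. Alternatives by peak score were not run because the lists hold none, and promoter windows were not run for lack of an annotation of mm9.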

Other observations

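The test of the tag was planned before its result was seen, and none of the tests of lists here was chosen afterwards.

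Several gene lists stood apart little from other genes at 24 h of auxin. G2 and M phase genes had 22 of 52 members higher and 10 lower (22 and 11 adjusted over the list alone, camera adjusted p = 0.0889), with the spindle gene Psrc1 and the phosphatase Cdc25b higher. Immediate early genes had 5 of 17 higher and 4 lower (6 and 4 adjusted over the list alone, adjusted p = 0.493). Polycomb and INO80 subunits had 9 of 44 higher and 16 lower (9 and 17 adjusted over the list alone, adjusted p = 0.161), and chromatin architecture factors 5 of 32 higher and 11 lower (5 and 11 adjusted over the list alone, adjusted p = 0.318). Cytosolic ribosomal proteins had 7 of 79 higher and 17 lower (4 and 6 adjusted over the list alone, adjusted p = 0.161), interferon response genes 8 of 19 higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.0665), and mitochondrially encoded genes 1 of 15 higher and 1 lower (1 and 0 adjusted over the list alone, adjusted p = 0.892). The single pluripotency marker tested did not pass.

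A hypothesis was that the degron tag acts like a partial loss of YY1 before any auxin is added. Then genes lower after 4 h of auxin in both TT-seq and RNA-seq should lie lower in untreated tagged cells than in parental cells. Of 371 such genes 330 were measured, and with the replicate block their median log2 fold change was −0.01 in the YY1-AID subline (camera p = 0.544) and 0.06 in subline 3 (p = 0.0711, and p = 0.845 and 0.58 with an estimated correlation). The test was negative: the genes that fell after auxin did not pass as lower in either tagged subline. The genes higher in both assays (64 of 75 measured), outside the prediction, had medians of 0.02 in the subline (camera p = 0.941) and 0.10 in subline 3 (p = 0.152, 32.8% below 0), and p = 0.934 and 0.209 with an estimated correlation.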
